A study of Mus musculus with 3 samples.

How the data were processed

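RNA of the aortic arch of LDLR-/- mice was sequenced in 3 libraries, 1 per group, and a gene table with a column for each library was used. Per the labels, tissue was flash frozen, RNA was extracted with Trizol and libraries were built with an Illumina TruSeq RNA kit. The submitters' processing notes name the mm10 build, HISAT2 2.0.5, featureCounts 1.5.0, StringTie 1.3.3b and edgeR 3.32.0, without the role or order of each. The annotation release, the strand setting of the counting and any filter on reads are not given in the sources used here. Reads of a gene and of an overlapping antisense gene therefore cannot be told apart.

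The deposited read counts are whole numbers per gene, not normalized, for 22046 genes, of which 21909 (99.38%) are protein-coding and 95 are unlisted in GENCODE M21. The deposited FPKM values are the same counts scaled by the authors per gene length and library. For 8637 genes with more than 200 counts in every library, the ratio of count to FPKM between libraries was the same for all genes within 2.4e-07%, so the FPKM table served only as another scaling. Gene symbols were those of the tables, and coordinates came from GENCODE M21 on GRCm38, the assembly that mm10 names. Genes with near-identical copies or many processed pseudogenes are reported as uncertain, since the treatment of reads that match several places is not given.

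Library totals over the listed genes were 16599343 reads in the untreated, 17439674 in the saline and 17030106 in the oligonucleotide library. Counts were scaled with the TMM factors of edgeR 4.0.16 in R 4.3.3, which were 0.943, 1.02 and 1.04 in the same order, and are given as CPM, counts relative to the scaled library total. Log2 ratios were differences of log2 CPM with a prior count of 2. Each ratio has an exact conditional binomial (Clopper-Pearson) 95% interval from the read counts of both libraries. These intervals cover counting error only, not the spread between animals, dissections or library preparations. A count of 0 allows 3 reads, which is 0.192 CPM in the untreated, 0.168 CPM in the saline and 0.170 CPM in the oligonucleotide library.

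With 1 library per group no test across replicates was possible and no p-value was computed. Genes with a mean of at least 1 CPM over the 3 libraries, 13139 in number, were compared, and those with an absolute log2 ratio of at least 1 were counted in each direction. To set these counts in context, 100 sets of libraries without any difference were drawn at assumed biological coefficients of variation of 0.2 and 0.4. Each gene was drawn independently of the others. The groups, the comparisons, 50 gene lists, the rule for named genes and the other settings listed at the end were fixed before the data were examined. The lists hold 844 symbols, of which 7 had no match in the table (Ahsp, Trbc1, Trbc2, Ighm, Igkc, Xist and Tsix). For each list with at least 3 members at 1 CPM or more, the median log2 ratio was set against 10000 random lists of the same size matched on mean expression in 20 bins. A list is called apart where its median lies below percentile 2.5 or above percentile 97.5 of those random lists, which describes these libraries and is not a test.

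Named genes were the 10 highest and 10 lowest log2 ratios of each main comparison among genes with a mean of at least 5 CPM, leaving out predicted gene models, pseudogenes and antigen receptor segments. Up to 4 members of each list with a mean of at least 5 CPM and the largest absolute log2 ratio were added, together with Atp6ap2, Ldlr, Sort1, Lrp1, Pdha1, Pdhb, Cd68, Acta2 and Myh11. Genes named outside this rule are said to be so.

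The procedure was tested on simulated Poisson counts, with counting error only, for the comparison of the saline with the untreated library. The test covered 13139 genes with 200 changed by known amounts. The procedure found 97.0% of genes changed by 1.5 and 98.0% of genes changed by 3 on the log2 scale at least 2-fold apart, and 0.131% of unchanged genes. The counting intervals held the true ratio for 95.1% of genes. Of 100 random unchanged lists of 20 genes, 4.0% were called apart, and of 100 lists shifted by 0.3 on the log2 scale, all were. None of these figures covers the spread between animals or dissections.

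The same quantities were computed again with DESeq2 1.42.0 size factors, library totals, prior counts of 0.5 and 5, no filter on low counts, a mean of at least 5 CPM, the deposited FPKM values as log2(FPKM + 1) and log2(FPKM + 0.1), and TMM factors computed without the muscle, adipocyte, erythroid and mitochondrially encoded genes. Settings chosen after seeing the data were counts without the genes of the T cell, thymocyte, B cell, adipocyte, muscle and erythroid lists, and counts of genes whose counting interval also excluded equal levels. Scaling by library totals moved the median of all genes by 0.12 for the saline against the untreated library and by 0.14 for the oligonucleotide against the untreated library on the log2 scale, so ratios of that size depend on the scaling. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.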

Results

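The data were 3 RNA-seq libraries of the aortic arch of LDLR-/- mice, 1 library per group. These mice lack the low-density lipoprotein receptor, which clears cholesterol-rich particles from blood, and form arterial plaques on a fatty diet. The untreated mice were 8 weeks old. The saline group was 12 weeks old after 4 weeks on a 42% Western-type diet with saline injections. The oligonucleotide group had the same age and diet, with weekly injections of antisense oligonucleotides against the (pro)renin receptor at 3.0 mg/kg/week. The label names them (P)RR G-ASOs, and what the G- form means for the tissue they act in was not examined here. The listed genes held 16599343 reads in the untreated, 17439674 in the saline and 17030106 in the oligonucleotide library. The labels do not say whether a library came from 1 mouse or from a pool, and no difference reported here has a replicate check. Intervals are 95% counting intervals, and levels are CPM, counts relative to the TMM-scaled library total.

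The transcript targeted by the oligonucleotide was lower in the library of that group. Atp6ap2, which encodes the (pro)renin receptor, an accessory subunit of the vacuolar proton pump that also binds renin and prorenin, lies on chromosome X from 12587801 to 12617049 (GRCm38, ENSMUSG00000031007). It stood at 72.6 CPM in the untreated, 76.0 CPM in the saline and 52.0 CPM in the oligonucleotide library. The log2 ratio of oligonucleotide to saline was -0.55 (interval -0.67 to -0.42), a ratio of 0.685, and that of saline to untreated was 0.07 (interval -0.05 to 0.18). Over all 13139 compared genes the log2 ratios of oligonucleotide to saline had a standard deviation of 0.45. Some other genes were lower still, such as Myocd at -0.75 and Eln at -0.66. The ratio alone therefore does not show that the oligonucleotide lowered its target in the arch. Ldlr, the gene disrupted in these mice, lies on chromosome 9 from 21723483 to 21749919 (ENSMUSG00000032193) and stood at 6.90, 10.3 and 6.74 CPM in the same order. Counts summed over the whole gene do not show whether reads came from the removed part, so they do not check the genotype.

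The first comparison set the saline library against the untreated library and addresses the arch after 4 weeks of the diet, with age and saline injections differing too. Genes of macrophages and antigen presentation and most measured chemokine genes were higher in the saline library, and genes of contractile smooth muscle and adipocytes and the elastin gene were lower. Spp1, which encodes the matrix protein osteopontin, stood at 136.0 CPM against 4.60 CPM, a log2 ratio of 4.85 (interval 4.55 to 5.24). Eln, which encodes elastin, stood at 3568 CPM against 10119 CPM, a log2 ratio of -1.504 (interval -1.52 to -1.49). Transcripts of immature T cells were also higher in the saline library, and so was Prss16, a serine protease gene of the thymic epithelium, with a log2 ratio of 5.77 (interval 4.93 to 8.19).

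Of 22 lesional macrophage genes, 13 were at least 2-fold higher in the saline library and none was 2-fold lower, with a median log2 ratio of 1.23 (0.76 on the log2(FPKM + 1) scale). Cd68, a lysosomal glycoprotein gene used to mark macrophages, had a log2 ratio of 2.10 (interval 1.83 to 2.40), and Ctss, the cathepsin S gene, 2.52. The list of foamy macrophage genes, 12 of whose 22 members stand in another list too, had a median of 1.16. In it, the elastase gene Mmp12 had a log2 ratio of 3.46, Gpnmb of 2.25 and Atp6v0d2 of 2.28. All 9 class II antigen presentation genes were above 0, with a median of 2.12, among them H2-Aa at 2.25 and H2-Eb1 at 2.22. The cytokine and chemokine list had a median of 1.38 over 15 measured genes, of which 11 were at least 2-fold higher and 2 at least 2-fold lower. Its monocyte attractant genes Ccl2 and Ccl8 had log2 ratios of 4.64 (interval 3.66 to 8.62) and 3.27 (interval 2.34 to 5.69) that rest on 2 and 4 untreated reads. The acute phase gene Saa3 and the receptor gene Slamf7, at 4.71 (interval 3.73 to 8.68) and 4.49 (interval 3.50 to 8.46), also rest on 2 untreated reads each. Adhesion molecule genes had a median of 0.69, with Vcam1, which binds leukocytes to activated endothelium, at 1.65 and Selp at 1.40. Interferon response genes had a median of 0.58 (0.36 to 0.70 across other settings), and 4 of the 22 were at least 2-fold higher. All these lists were apart from expression-matched random lists, but so were most others, so being apart does not single them out. Of 49 lists, 25 lay above and 11 below the random range, where 2.45 random lists would lie outside it. For oligonucleotide against saline 27 lay above and 6 below, and for oligonucleotide against untreated 24 and 7.

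Blood and lymphoid genes moved with the same comparison. The thymocyte list had a median log2 ratio of 4.11 over 6 measured genes and the T cell list 3.05 over 10 (1.65 and 1.22 on the log2(FPKM + 1) scale), with Tcf7, a transcription factor gene of early T cells, at 3.82 and Cd4 at 3.03. The neutrophil list stood at 2.11 over 5 genes, and the erythroid list at 1.502, with the haem synthesis gene Alas2 at 1.56. Hba-a2, at 1.57, has a near-identical copy in Hba-a1, whose ratio is the list median of 1.502, so both values are uncertain. The 3 measured B cell genes had a median of 1.55, which was inside the range of matched lists. Cell cycle genes had a median of 0.73, with Mki67, a marker of proliferating cells, at 1.52. The saline library may hold thymus tissue, as described below, and its share of the thymocyte, T cell and cell cycle medians was not estimated. In the oligonucleotide against the untreated library, which leaves out the saline library, the cell cycle median was 1.11.

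Contractile smooth muscle genes were lower by less than 2-fold. All 20 members were below 0, none was 2-fold apart, and the median log2 ratio was -0.40 (-0.29 when scaled by library totals). Acta2, the smooth muscle actin gene, was at -0.39, Myh11, the smooth muscle myosin gene, at -0.32 and Myocd, a transcriptional coactivator of both, at -0.64. The list of modulated smooth muscle genes, 10 of whose 17 measured members stand in another list, had a median of 0.67, with Timp1 at 1.62 and Lgals3 at 1.31. Collagen and matrix genes had a median of -0.24, with 1 of 24 at least 2-fold lower and 5 above 0. That gene was Eln, followed by Sparc at -0.96 and the collagen crosslinking gene Lox at -0.92. Matrix protease genes had a median of 0.21, with 7 of 21 at least 2-fold higher. Immediate early genes had a median of -0.32, with Cyr61 at -1.73, Fosb at -1.55 and Nr4a1 at -1.16, and TGF-beta signalling genes a median of -0.20, with Ctgf at -0.89.

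Adipocyte genes were lower in the saline library, by a median log2 ratio of -0.59 for the white and shared list and of -0.56 for the brown list. Pck1, a gene of glycerol and glucose synthesis, was at -1.32 and the glycerol channel gene Aqp7 at -1.52. Beside them, fatty acid and triglyceride synthesis genes had a median of -0.16, with Dgat2 at -0.83 and Scd2 at 0.96. Cholesterol efflux genes had a median of 0.23, with Apoe at 1.89 and the sterol exporter gene Abcg1 at 1.79. Cholesterol synthesis genes had a median of -0.07, which became 0.05 when scaled by library totals, and were not apart from matched lists. Lipoprotein receptor genes had a median of -0.13, also inside that range. In this list the scavenger receptor gene Msr1 was at 1.73, Sort1 at 0.15 and Lrp1 at -0.08, or 0.04 with library totals. Pdha1 and Pdhb, subunit genes of pyruvate dehydrogenase, were at -0.40 and -0.20, in a list with a median of -0.17. Renin-angiotensin genes had a median of 0.28, with Anpep at 1.00 and Mme at -0.67.

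Among 13139 genes, 689 were at least 2-fold higher and 84 at least 2-fold lower in the saline library. Simulated libraries without any difference gave on average 167 higher and 159 lower at an assumed coefficient of variation of 0.2 (at most 195 and 191 in 100 draws). At 0.4 they gave 1559 and 1563, more than was observed, so 0.4 is too large for most genes here. The simulated directions were nearly even, unlike the observed 689 and 84. Genes were drawn independently, so even directions were built into the simulation. Genes that move together between animals or dissections could give uneven counts without an effect of the conditions. The true spread between animals is not known, so the counts do not show how many genes differ between the conditions. The total of 773 became 2028 without a filter on low counts, 318 at a mean of at least 5 CPM and 184 on the log2(FPKM + 1) scale. Gapdh (-1.77) and Srp54b (-2.64) were among the 10 lowest ratios, but Gapdh has many processed pseudogenes and Srp54b near-identical neighbours, so both are uncertain.

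**Figure D1:**
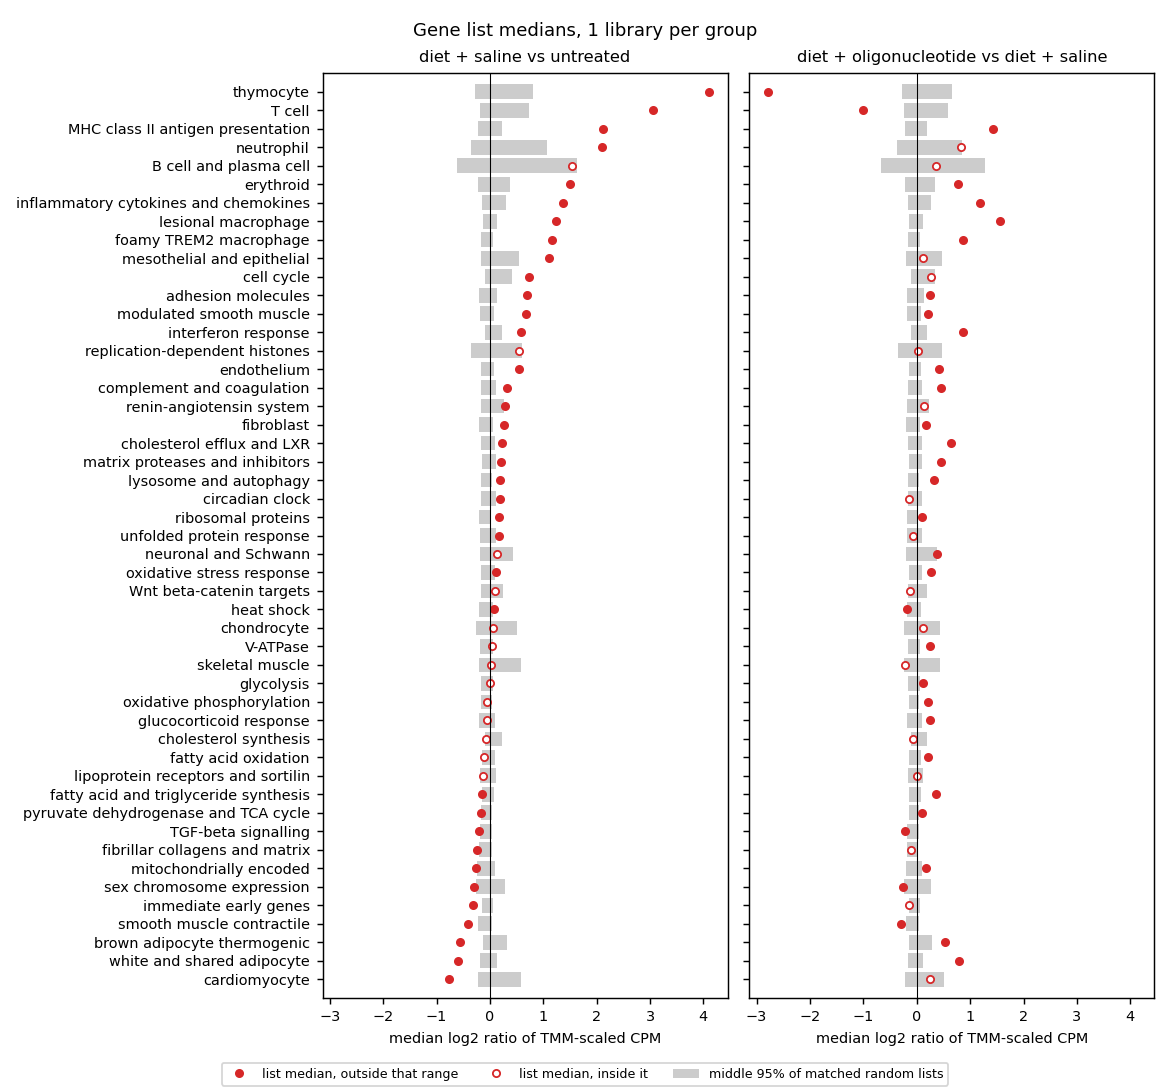
Median log2 ratio of TMM-scaled CPM for each gene list with at least 3 measured members, for the saline against the untreated library (left) and the oligonucleotide against the saline library (right), with grey bars for the middle 95% of 10000 expression-matched random lists; filled points lie outside that range. The lesional macrophage list lies at 1.23 and 1.56, the contractile smooth muscle list at -0.40 and -0.30, the white adipocyte list at -0.59 and 0.79, and the thymocyte list at 4.11 and -2.79.

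The second comparison set the oligonucleotide library against the saline library, both on the diet, and addresses the effect of inhibiting the (pro)renin receptor in mice that form plaques. Macrophage, interferon response and class II antigen presentation genes were higher still in the oligonucleotide library, and contractile smooth muscle genes were slightly lower still. Cd68 stood at 110.8 CPM against 33.7 CPM, a log2 ratio of 1.71 (interval 1.59 to 1.85). Adipocyte genes, lower in the saline than in the untreated library, were higher in the oligonucleotide than in the saline library. Thymocyte genes, high in the saline library, were lower in the oligonucleotide library, with Tcf7 at -2.47, and the thymic epithelial gene Prss16 was at -4.57 (interval -5.70 to -3.98).

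Of 22 lesional macrophage genes, 21 were at least 2-fold higher in the oligonucleotide library, with a median log2 ratio of 1.56. Adgre1, which encodes the macrophage surface protein F4/80, was at 2.27 (interval 2.03 to 2.56), the complement component gene C1qa at 1.96 (interval 1.87 to 2.06) and the chemokine receptor gene Ccr2 at 1.87. Foamy macrophage genes had a median of 0.87, with 10 of 22 at least 2-fold higher, among them the lipid-sensing receptor gene Trem2 at 1.52, Spp1 at 1.53 and Cd5l at 2.12. Cytokine and chemokine genes had a median of 1.18. The highest ratio among genes with a mean of at least 5 CPM was that of Ccl8, at 3.89 (interval 3.56 to 4.33), followed by Clec12a at 2.62 and Saa3 at 2.47. The 9 class II genes were all above 0, with a median of 1.43, H2-Eb1 at 1.62 and Cd74, the invariant chain gene, at 1.58. Interferon response genes had a median of 0.87 (0.64 over members with a mean of at least 5 CPM), with 9 of 22 at least 2-fold higher. Irf7, a transcription factor gene of the type I interferon response, was at 2.23, Oas2 at 2.12 and Zbp1 at 1.87. Complement and coagulation genes had a median of 0.46, with C4b at 1.47. Adhesion molecule genes had a median of 0.24, and none of 11 was 2-fold apart.

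Lysosomal genes had a median of 0.32 over 25 members, with the protease genes Lgmn at 0.91 and Ctsd at 0.80. V-ATPase genes, whose products form the proton pump that the (pro)renin receptor belongs to, had a median of 0.25, with Atp6v0d2 at 1.23 and Tcirg1 at 0.65. The renin-angiotensin list, which holds Atp6ap2, had a median of 0.14 that was inside the range of matched lists. In it Anpep was at 0.98 and Prcp at 0.50. Cholesterol efflux genes had a median of 0.64, with the phospholipid transfer gene Pltp at 1.46, Apoe at 1.12 and Abcg1 at 1.02. Cholesterol synthesis genes had a median of -0.07, inside the range of matched lists, with Dhcr24 at -0.89 and Sqle at -0.47. Lipoprotein receptor genes had a median of 0.01 (-0.01 on the log2(FPKM + 1) scale), with Msr1 at 1.27, Ldlr at -0.61 (interval -0.96 to -0.27), Sort1 at -0.25 (interval -0.33 to -0.16) and Lrp1 at -0.03. Pdhb was at 0.10 and Pdha1 at -0.01, or 0.01 with library totals, in a pyruvate dehydrogenase and citric acid cycle list with a median of 0.10.

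White and shared adipocyte genes had a median of 0.79, with 14 of 16 above 0 and 1 at least 2-fold lower. Brown adipocyte genes had a median of 0.53, with 10 of 14 above 0 and 4 below. The adipokine genes Cfd and Adipoq were at 1.28 and 1.09, and Ucp1, which encodes the uncoupling protein of brown fat, was at 1.61. Metabolic lists moved with them. Fatty acid and triglyceride synthesis genes had a median of 0.36, with Dgat2 at 1.22. Fatty acid oxidation genes had a median of 0.21, with Hadhb at 0.54, and oxidative phosphorylation genes also of 0.21, with 23 of 24 above 0 and none 2-fold apart.

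Contractile smooth muscle genes had a median of -0.30, with 19 of 20 below 0, Myocd at -0.75, Myh11 at -0.30 and Acta2 at -0.22. The other member, Pln, was at 1.20 on few reads and is named outside the rule for genes. Eln was at -0.66 (interval -0.68 to -0.64) and Lox at -0.65, while Col3a1 was at 0.47, and the collagen and matrix list had a median of -0.10 that was inside the range of matched lists. Modulated smooth muscle genes had a median of 0.20. TGF-beta signalling genes had a median of -0.23, with Serpine1, which encodes an inhibitor of plasminogen activation, at -0.97 and Ctgf at -0.71. T cell and thymocyte lists had medians of -1.02 and -2.79, with Tcf7 at -2.47 and Satb1 at -1.10. Across other settings the thymocyte median lay between -2.92 and -1.66. Over the 3 T cell genes with a mean of at least 5 CPM the median was 0.21. The erythroid list was at 0.77.

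Of 13139 genes, 527 were at least 2-fold higher and 89 at least 2-fold lower in the oligonucleotide library. The simulated libraries without any difference gave on average 157 higher and 160 lower at a coefficient of variation of 0.2, and 1563 and 1560 at 0.4. The total of 616 became 1670 without a filter on low counts, 260 at a mean of at least 5 CPM and 226 on the log2(FPKM + 1) scale. Among the 10 lowest ratios, Sumo2 (-2.33), Rps27 (-1.43) and Rps27a (-1.36) share sequence with processed pseudogenes and are uncertain.

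**Figure D2:**
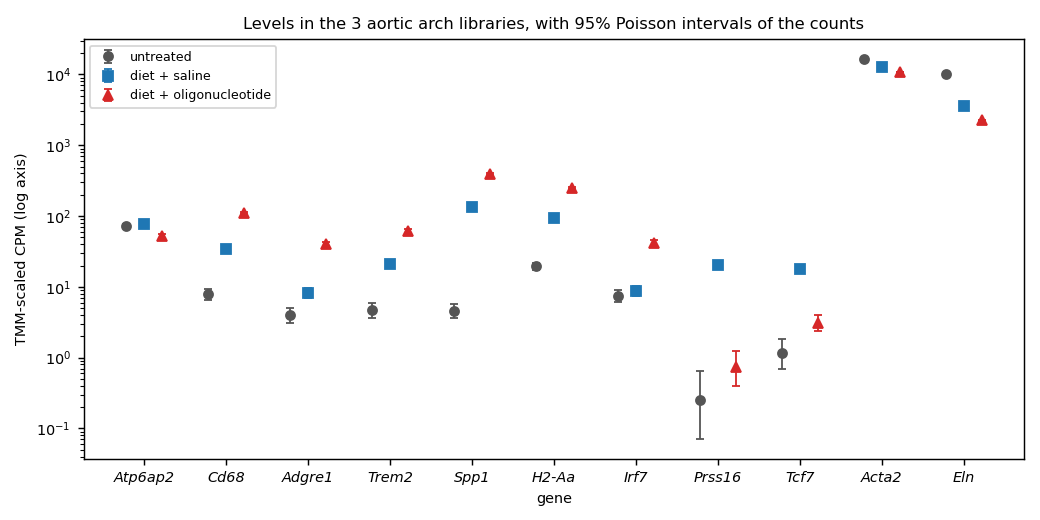
TMM-scaled CPM on a log axis for 11 genes in the untreated (circles), saline (squares) and oligonucleotide (triangles) libraries, with 95% Poisson intervals of the counts. Cd68 stands at 7.79, 33.7 and 110.8 CPM, Atp6ap2 at 72.6, 76.0 and 52.0 CPM, and Prss16 at 0.256, 20.2 and 0.736 CPM.

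The third comparison set the oligonucleotide library against the untreated library, and so leaves out the saline library with its thymocyte transcripts. It held 1192 genes at least 2-fold higher and 174 at least 2-fold lower, where simulated libraries without any difference gave on average 165 and 162 at a coefficient of variation of 0.2, and 1571 and 1566 at 0.4. The total of 1366 became 2734 without a filter on low counts, 723 at a mean of at least 5 CPM and 591 on the log2(FPKM + 1) scale. Lesional macrophage genes had a median log2 ratio of 3.04, class II genes of 3.63, cytokine and chemokine genes of 2.92, foamy macrophage genes of 2.25 and interferon response genes of 1.36. Contractile smooth muscle genes had a median of -0.64. The white adipocyte list, at 0.14, and the thymocyte list, at -0.15 with 2 of 6 members at least 2-fold higher, were inside the range of matched lists. The other cell type lists apart from and above matched lists had medians of 2.34 for erythroid, 1.81 for neutrophil, 1.72 for T cell, 1.23 for mesothelial and epithelial, 0.97 for modulated smooth muscle, 0.86 for endothelial and 0.38 for fibroblast genes. Those below had medians of -0.64 for cardiomyocyte and -0.25 for brown adipocyte genes (0.04 over members with a mean of at least 5 CPM). Blood and lymphoid genes thus differed in this comparison too.

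Of the 689 genes at least 2-fold higher in the saline than in the untreated library, 599 (86.9%) were also at least 2-fold higher in the oligonucleotide than in the untreated library. Of the 84 lower genes, 28 (33.3%) were lower in both. Both ratios share the untreated library, so part of this overlap arises without any effect. Simulated libraries without a difference shared 39.7 higher (23.9%) and 15.6 lower genes (9.83%) at a coefficient of variation of 0.2. At 0.4 they shared 664 of 1559 higher genes (42.6%) and 444 of 1563 lower genes (28.4%). Because genes were drawn independently, the simulation leaves out overlap from genes that move together between animals or dissections. Independent lists of these sizes would share 62.5 higher and 1.11 lower genes. From untreated to saline to oligonucleotide, 219 genes were at least 2-fold higher at both steps and 0 were at least 2-fold lower at both. Another 41 were higher and then lower, 9 of them in the T cell or thymocyte lists, and 33 were lower and then higher. The 41 also held the thymic epithelial gene Prss16, which is in neither list, so 9 is not a full count of thymic genes. Named outside the rule, Dntt (-5.20) and Rag1 (-5.04) fell most from saline to oligonucleotide, and Tbata, Krt5 and Krt8 were among the 41 too. These genes may come from thymus tissue in the saline library, as described below. The 41 are therefore not a count of genes that the oligonucleotide returned to the untreated level. Both steps share the saline library, so part of the 41 and the 33 arises without any effect.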

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

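The counts without cell type lists and the counts that also required an interval excluding equal levels were chosen after seeing the data. Among the planned and added settings, 29 of the 107 gene counts and target ratios moved by over 1.5 times or beyond their interval, 0 reversed and 78 did not. Of 1311 list medians 43 moved and 3 reversed, and of 2646 single gene ratios 135 moved and 1 reversed, where reversed means a changed sign of a median apart from matched lists or of a ratio whose interval excluded 0. Counting every change of sign, library totals alone altered that of 8 of 147 list medians and 3 of 378 single gene ratios, all within 0.15 of 0 before. Without a filter, genes 2-fold apart numbered 2028 (1419 higher, 609 lower) for saline against untreated, 1670 (1162 and 508) for oligonucleotide against saline and 2734 (2075 and 659) for oligonucleotide against untreated. At a mean of at least 5 CPM they numbered 318 (290 and 28), 260 (243 and 17) and 723 (611 and 112) in the same order, since fewer genes were counted. With log2(FPKM + 1), which shrinks low genes, they numbered 184 (168 and 16), 226 (208 and 18) and 591 (521 and 70). Lower genes numbered 57 for oligonucleotide against saline with log2(FPKM + 0.1) and 110 for oligonucleotide against untreated with library totals. With log2(FPKM + 1) the saline against untreated medians were 0.76 for lesional macrophage and 1.65 for thymocyte genes, and with library totals that of contractile smooth muscle was -0.29. At a mean of at least 5 CPM the interferon median of oligonucleotide against saline was 0.64. Some list medians outside the span from the median lower to the median upper counting bound of their members were not counted as moved. This span is not an interval of the list median itself. For oligonucleotide against saline, the thymocyte median reached -1.66 (span -4.08 to -2.30) and the lesional macrophage median 1.33 (span 1.36 to 1.85). Reversed in this sense were Lrp1 in saline against untreated with library totals, 0.0399, and at a mean of at least 5 CPM the clock median of saline against untreated, -0.0745, the T cell median of oligonucleotide against saline, 0.21, and the brown adipocyte median of oligonucleotide against untreated, 0.0403. The latter medians had fewer members, and the cause of the other moves was not tested. Across the other settings the totals lay between 630 and 879, 504 and 651, and 1227 and 1493, the Atp6ap2 ratio between -0.55 and -0.53, and the shared higher genes numbered 572 with DESeq2 size factors. No paired analysis was possible because each group had 1 library.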

Other observations

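The tests of scaling, adipose tissue, blood, macrophage make-up, single animals, mature T cells and the difference of interferon and macrophage medians below were chosen after the result was seen, and those of adipose tissue and macrophage make-up replaced earlier tests whose values are also given. Endothelial genes had a median log2 ratio of 0.54 in the saline against the untreated library and of 0.42 in the oligonucleotide against the saline library. Among them Plvap, a gene of fenestrated capillaries, was at 1.43 and 0.84, and the tight junction gene Cldn5 at 1.12 and 0.85. Fibroblast genes had medians of 0.26 and 0.18. Mesothelial and epithelial genes had medians of 1.10 and 0.11, with the mesothelial gene Upk3b at 1.10 and 0.12, but 2 of 11 were at least 2-fold lower in the latter comparison. The keratin genes Krt5 and Krt8, named outside the rule, were high in the saline library only. They had 0, 105 and 12 reads and 18, 127 and 50 reads in the untreated, saline and oligonucleotide libraries. Cardiomyocyte genes had medians of -0.76 and 0.24, with Tnnt2 at -0.87 and -0.07. Complement and coagulation genes had a median of 0.32 in the first of these comparisons, with C3 at 1.01. The Schwann cell and neuronal list had medians of 0.13 and 0.39, the chondrocyte list of 0.05 and 0.11 and the skeletal muscle list of 0.03 and -0.23. Of these, the chondrocyte and skeletal muscle medians, the first Schwann cell and the latter cardiomyocyte and mesothelial medians were inside the range of matched lists. The parathyroid and thyroid list had 1 measured gene and no median.

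Oxidative stress genes had medians of 0.11 and 0.27, with the haem oxygenase gene Hmox1 at 1.45 and 1.58. Unfolded protein response genes had medians of 0.17 and -0.07, and heat shock genes of 0.07 and -0.19. Clock genes had medians of 0.18 and -0.15, and the first of these was -0.07 over members with a mean of at least 5 CPM. The clock repressor gene Nr1d1 was at -0.86 and Cry1 at 1.06 in the oligonucleotide against the saline library. Immediate early genes had a median of -0.14 in that comparison and matrix protease genes of 0.45. The lysosomal and V-ATPase lists had medians of 0.20 and 0.04 in the saline against the untreated library. Mitochondrially encoded genes were at -0.26 and 0.17, ribosomal protein genes at 0.18 and 0.10, and replication-dependent histone genes at 0.54 and 0.01. Cell cycle, neutrophil and B cell genes had medians of 0.27, 0.83 and 0.36 in the oligonucleotide against the saline library, all inside the range of matched lists. Wnt target genes were at 0.09 and -0.13. Glucocorticoid response genes were at -0.06 (0.06 with library totals) and 0.25, glycolysis genes at -0.01 (0.11 with library totals) and 0.11, oxidative phosphorylation genes at -0.05 (0.07 with library totals) and fatty acid oxidation genes at -0.12. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty, the measured members of the sex chromosome list, were read in all 3 libraries, with medians of -0.29 and -0.26.

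Macrophage genes were higher in the oligonucleotide than in the saline library, and the median of the lesional macrophage list exceeded that of all compared genes by 1.57, which argues against scaling, since a scaling error moves all genes alike. This median exceeded the white adipocyte median by 0.77 (by 2.90 against the untreated library, the earlier test). The median of macrophage genes with little expression in blood exceeded the erythroid median by 1.02. That erythroid median, 0.77, was the ratio of Hba-a2, which is uncertain because of its near-identical copy. Of the 7 measured erythroid genes, 1 was at least 2-fold higher in this comparison. So neither adipose tissue of unchanged make-up nor blood alone would give the difference from the saline library. Against the untreated library the medians of those macrophage genes and of erythroid genes were close, at 2.47 and 2.34, so there the test does not argue against blood. Whether the make-up of the macrophages changed stays open: in the earlier test the medians of resident-type genes (1.14) and of foamy macrophage-restricted genes (1.41) differed by -0.27, inside the bound of 0.3 for the same make-up. In the test that replaced it, the counting interval of the position of the saline library between the others excluded the list median of 0.206 for 11 of 21 genes, the fewest that passed its bound and too few had Mertk counted, whose interval between oligonucleotide and untreated was not above 0, and it set single libraries against counting error only. With 1 library per group, an effect of the oligonucleotide cannot be told apart from a difference between single animals or dissections.

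Thymocyte transcripts in the saline library may come from thymus tissue in the dissection, since the thymus lies next to the arch. Reads of 6 thymic epithelial genes, written down as a list before their values were looked at, summed to 301 in the saline library against 107 in the untreated and 103 in the oligonucleotide library, with Tbata at 123, 8 and 6 and Psmb11 at 30, 0 and 0. Pax1, at 128, 98 and 95 reads, gave most of the sum in the other libraries. Rag1, Rag2, Dntt and Ptcra, which mature T cells lack, summed to 381 reads against 10 and 7, which argues against mature T cells of the lesion as the source of these transcripts. The share of Cd4, other T cell genes and cell cycle genes that thymus tissue would bring was not estimated. The T cell and cell cycle medians of the saline library therefore stay open.

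Interferon response genes were higher in the oligonucleotide than in the saline library, and whether a larger macrophage share alone gave this stays open. For 15 of the 16 measured genes of a second interferon list, written down before its values were looked at and without Herc6 for the same reason as Mertk, the median position of the saline library between untreated (0) and oligonucleotide (1) was 0.304, inside the range from 0.117 to 0.318 between the 10th and 90th percentiles of single macrophage genes, which is a weak test of a median. The median was 0.0979 above that of the macrophage genes (95% bootstrap interval over genes 0.0345 to 0.301), and that of the first interferon list 0.0576 above it (interval -0.114 to 0.205). A higher position puts more of the rise between untreated and saline and less between saline and oligonucleotide. The bootstrap treats genes as independent and covers no spread between animals. In the first list, without Ifit2 for that reason too, 14 of 21 genes had counting intervals that met the macrophage range. Wide intervals from few reads meet it easily, so this is weak agreement. Below it lay 3 genes, Usp18, Rsad2 and Irf7 (0.0418), and above it 4, Gbp2, Gbp3, Gbp7 and Irf1 (0.681), some named outside the rule. The positions of this list ran from -0.0247 to 0.533 between the 10th and 90th percentiles, a wider span than that of the macrophage genes. A macrophage share alone was thus not shown to account for the list. A response to the oligonucleotide itself is not excluded, and no library of a control oligonucleotide was analysed here.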
